A study of Rattus norvegicus with 15 samples.

How the data were processed

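Deposited data were 15 tables of counts per gene, 1 per library, from dispersed islet cells of 10-day-old rats transfected with a control mimic or a miR-17-5p mimic. The deposited counts had been made by the authors before deposit: reads were aligned to the rat build rn5 with TopHat2 2.0.10 and Bowtie2 and counted per gene with HTSeq, per the submitters' processing notes, and the versions of Bowtie2 and HTSeq are not given in the sources used here. The same notes name DESeq and edgeR, with versions not given in the sources used here. RNA was extracted with Trizol, mRNA libraries were poly(A) selected with oligo(dT), RISC libraries were made from RNA bound by a monoclonal antibody against Ago2, and libraries were single-end and not strand-specific, per the labels' protocols. For RISC libraries the labels state no poly(A) selection. The series tables hold 15 columns, of which 15 equalled 1 library each by position.

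Tables held 17055 genes named by symbol, and 14175 of these symbols were found in a RefSeq table of assembly GRCr8, used for names only. The summary lines of the counting program stayed out of library sizes and tests: alignments not unique made up 15.0% to 31.2% and ambiguous ones 0.151% to 0.454% of each library, and the line for reads in no gene held 0. Because counting used no strand, overlapping and antisense genes cannot be told apart, and values of near-identical copies such as Ins1 and Ins2, globins, actins, ribosomal proteins and Atp5g1 are uncertain. No pair of libraries of a group held identical values (chi-square per degree of freedom 7.08 to 327). At the depth of the control RISC libraries 3 counts correspond to 0.224, 0.346 and 0.717 CPM, and a fold against a group at 0 is given against this floor of 3 counts per library. Such floors cover counting error only.

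Groups were taken from the sample titles. The comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined. Counts were tested in R 4.3.3 with edgeR 4.0.16, using trimmed mean of M values (TMM) factors, filterByExpr, robust quasi-likelihood fits and two-sided quasi-likelihood F-tests, with Benjamini-Hochberg adjusted p under 0.05 as called. Adjusted p values of genes in the report come from this test unless another tool is named. The comparisons were miR-17-5p against control in mRNA, the same in RISC, the difference of both in a model of 15 libraries with 1 mean per group, and RISC against mRNA in control cells. Genes called in both single comparisons were counted per direction against the number for independent lists and by Fisher's exact test across genes. CPM, counts scaled to library size, use the TMM factors of each comparison. The common biological coefficient of variation was 0.305 in mRNA, 1.23 in RISC, 0.871 in the difference and 1.20 between library types. Each fit gave a gene 1 spread over all its libraries, so fits with both library types assume the same spread in mRNA and RISC.

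The 26 gene lists were written from general knowledge before testing. They covered miR-17 family targets, islet hormones, beta cell transcription factors, glucose sensing and secretion, genes kept low in beta cells, cell cycle, transforming growth factor beta signalling, insulin signalling, autophagy, unfolded protein response, interferon response, inflammation, glycolysis, respiration, ribosomal proteins, microRNA machinery, histones, immediate early genes, and markers of alpha, delta and PP, acinar, duct, endothelial, stellate, macrophage, Schwann and red blood cells. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and with an estimated correlation as alternative. Fry, the other alternative, tests a list against no change rather than against the other genes. Lists were also scored per library as the mean log2 CPM of their members, and scores were compared by exact two-sided permutation. In RISC 24 lists had enough members, and acinar and red blood cell markers had not.

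Genes named in the text were, per comparison, the 8 with the smallest p in each direction among those called with a mean log2 CPM of at least 4, up to 4 members per list, Ins1, Ins2, Gcg, Sst, Cdkn1a, E2f1, Bcl2l11, Tgfbr2 and 1 gene that is not reported here, and the 10 genes nearest to falling in mRNA and rising in RISC. Examples from the genes higher in both, and Mgp and Postn in the closing part, were picked after their values were seen.

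Alternatives were DESeq2 size factors, upper quartile factors, no filter, a mean of at least 50 counts, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, a replicate block, replicate numbers with both library types, and each replicate left out. Where a comparison used both library types, the mRNA and the RISC library of that replicate number were left out together. Chosen after seeing the data were a mean of at least 500 counts, library sizes without Ins1, Ins2, Rn45s and Rn28s, the stellate score as a covariate, and leaving out miR-17-5p replicates 1 and 2 together. The steps were tested on simulated counts with 200 genes changed by 2, 4, 16 or 64-fold. In simulated mRNA (10886 genes) edgeR recovered 46.9%, 77.6%, 100% and 100% of them, with 5.49% of 164 calls false. In simulated RISC (8800 genes) it recovered 0%, 4.35%, 16.7% and 32.6%, for the difference (11149 genes) 0%, 2%, 22.4% and 40%, and between library types (9262 genes) 0%, 0%, 11.1% and 29.3%. DESeq2's false share was 11.5%, 58.4%, 41.5% and 67.6% in these 4 comparisons. Before the added changes each simulated gene had the same mean in all libraries. Real differences between library types and genes at 0 in a whole group were thus not imitated, and these rates need not hold there. Tests of seed sites in 3' UTRs were planned and not run, since no 3' UTR sequences of the build were at hand.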

Results

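The series measured transcripts of islet cells from 10-day-old Sprague-Dawley rats. The islets were dispersed into single cells and transfected with a miR-17-5p mimic, a synthetic RNA that adds this microRNA, or with a control mimic. Poly(A) RNA was sequenced as mRNA libraries. In parallel, Ago2, the Argonaute protein that carries microRNAs in the RNA-induced silencing complex (RISC), was immunoprecipitated, and the RNA bound to it was sequenced as RISC libraries. There were 3 control and 5 miR-17-5p mRNA libraries, and 3 control and 4 miR-17-5p RISC libraries, 15 in all. The labels call the libraries biological replicates, but numbers in titles and descriptions differ, so p-values measure only the spread between these libraries, which may be technical.

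The control mRNA libraries 1, 2 and 3 held 10207925, 8297465 and 3379456 counts. The miR-17-5p mRNA libraries 1, 2, 4, 5 and 6 held 21056240, 7677357, 6707108, 5870265 and 9538499. The control RISC libraries 1, 2 and 3 held 13420403, 8662423 and 4185123, and the miR-17-5p RISC libraries 2, 4, 5 and 6 held 12733872, 9656282, 9213279 and 7819020. Ins1 and Ins2, the rat insulin genes, together took 26.2% to 41.8% of the counts in mRNA libraries and 0.947% to 1.97% in RISC libraries. Rn45s, the ribosomal RNA precursor, took 3.13% to 12.8% of mRNA counts and 23.6% to 42.6% of RISC counts.

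The 2 kinds of RISC library differed in how many genes they held. Thinned to the same total of 4185123 counts, control RISC libraries detected 6497 ± 807 genes (SD, n = 3) and miR-17-5p RISC libraries 9871 ± 751 (SD, n = 4). This difference had an exact two-sided permutation p of 0.0286, the smallest that 35 splits allow. Thinned mRNA libraries detected 11717 ± 509 (SD, n = 3) and 11864 ± 539 genes (SD, n = 5).

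**Figure D1:**
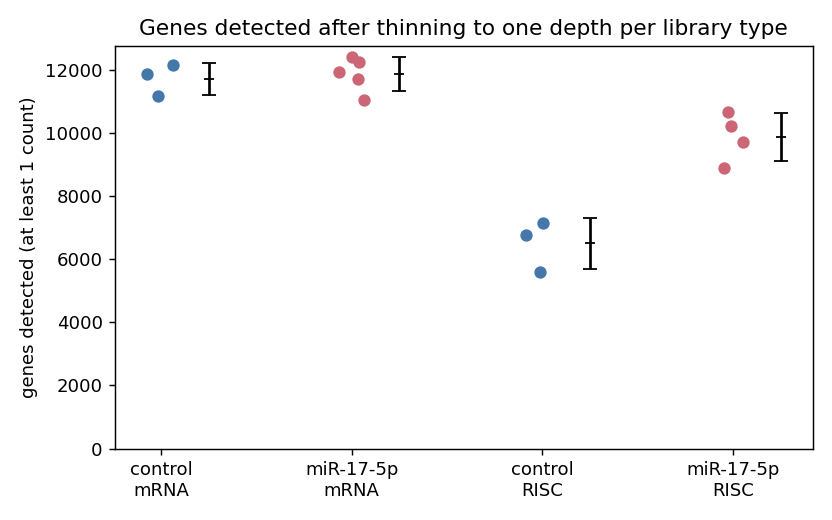
Genes with at least 1 count per library (vertical axis) in the 4 groups, each library thinned to the smallest total of its type; points are libraries, and bars show the mean and SD. Control RISC libraries lie between 5589 and 7132 genes and miR-17-5p RISC libraries between 8901 and 10646.

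The first comparison asked which transcripts changed in poly(A) RNA after miR-17-5p was added. Several genes of contractile and matrix-producing cells rose and a few endocrine genes fell. Acta2, smooth muscle actin, rose from 564 ± 157 CPM in control to 2207 ± 578 CPM in miR-17-5p libraries (SD, n = 3 and 5). Fn1, fibronectin, rose from 1010 ± 326 to 3666 ± 1215 CPM, and Tgfb2, a ligand of the transforming growth factor beta family, from 11.6 ± 2.07 to 42.6 ± 3.41 CPM. Ghrl, which encodes ghrelin, fell from 64.6 ± 18.3 to 29.8 ± 5.68 CPM, and Cxcl10, an interferon-inducible chemokine, from 55.5 ± 27.1 to 11.7 ± 3.40 CPM. Ins1 and Ins2 did not pass the test.

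In all, 429 of 11077 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 344 of them higher and 85 lower with miR-17-5p. Log2 fold changes are given below with their standard errors. The gene with the smallest p was Akap12, a scaffold for protein kinases A and C (1.64 ± 0.14, edgeR adjusted p = 1.8e-04). Next among the higher genes came Tgfb2 (1.85 ± 0.19, adjusted p = 7.8e-04) and Mylk, myosin light chain kinase (1.76 ± 0.18, adjusted p = 7.8e-04). Fam198b rose by 2.16 ± 0.23 and Fbln5, the elastic fibre protein fibulin 5, by 2.17 ± 0.24. Smaller rises were those of Adam19, a metalloprotease (1.69 ± 0.19), Amotl2, an angiomotin family member (1.48 ± 0.16), and Dpysl3, a cytoskeletal regulator (1.42 ± 0.16). Among lower genes Cxcl10 had a log2 fold change of -2.24 ± 0.33 (adjusted p = 0.0035) and Stmn2, a microtubule-binding stathmin of neurons, -1.37 ± 0.21 (adjusted p = 0.0046). Cdh23, a cadherin, fell by 1.26 and Egr1, an immediate early transcription factor, fell by 1.21. Ddx41, an RNA helicase, fell by 0.86, Kit, the stem cell factor receptor, fell by 0.82, and Sipa1l3 fell by 0.76. Ghrl had a log2 fold change of -1.13 ± 0.20 (adjusted p = 0.0089).

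**Figure D2:**
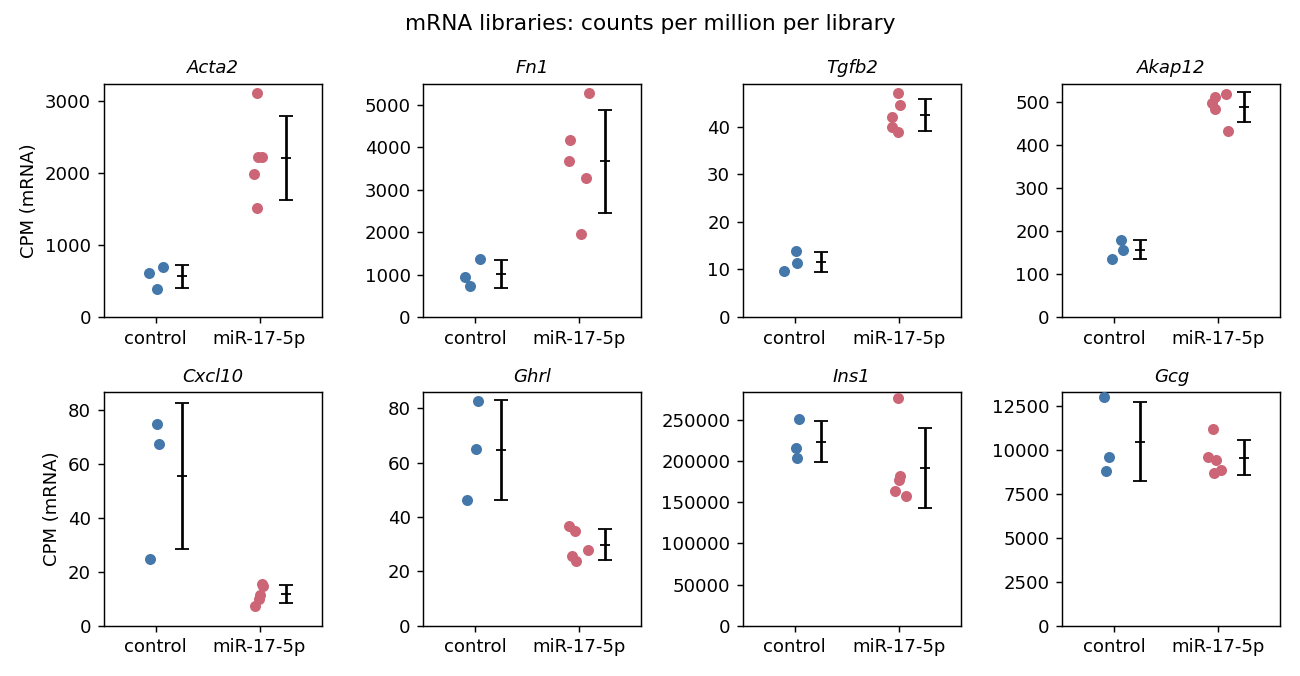
CPM (vertical axes, each from 0) of 8 genes in the mRNA libraries, control (n = 3) and miR-17-5p (n = 5); points are libraries, and bars show the mean and SD. Acta2, Fn1, Tgfb2 and Akap12 lie higher with miR-17-5p, Cxcl10 and Ghrl lie lower, and Ins1 and Gcg overlap.

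Stellate cell and fibroblast genes, which mark the contractile and matrix-producing cells of an islet preparation, formed the list with the most members higher over all genes. Of 17 tested members 10 rose over all genes tested and 10 when adjusted over the list alone, and none fell by edgeR. Beside Acta2 (1.97 ± 0.25, adjusted p = 0.0013) and Fn1 (1.86 ± 0.30, adjusted p = 0.0063), Sparc, a matrix glycoprotein, rose by 1.36 ± 0.25 and Thy1 by 1.12 ± 0.18. The list's camera test gave an adjusted p of 3.6e-06, and an adjusted p of 0.434 with an estimated correlation. The number of members called fell to 1 without control replicate 3, 3 without control replicate 2, and 6 without miR-17-5p replicate 4 or 5. The mean log2 CPM of the list was 7.86 ± 0.305 in control and 8.68 ± 0.419 in miR-17-5p libraries (SD, n = 3 and 5; exact permutation p = 0.0536, adjusted p = 0.169 over the lists). Genes of transforming growth factor beta and bone morphogenetic protein signalling also rose in 5 of 25 tested members, 6 adjusted over the list alone. Tgfb3 rose by 1.61 ± 0.22, Tgfb1 by 0.97 ± 0.22 and Id3, a target of this pathway, by 0.68 ± 0.15. This list had a camera adjusted p of 0.0013, and an adjusted p of 0.294 with an estimated correlation. It had 2 members called without control replicate 2 or 3 or miR-17-5p replicate 4 or 5.

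Of the 8 islet hormone genes tested, Ghrl and Pyy, peptide YY (-0.80 ± 0.17, adjusted p = 0.0183), passed the test over all genes, and 5 were lower adjusted over the list alone. By edgeR 0 hormone genes passed without control replicate 1 or 2, and 4 passed without miR-17-5p replicate 1. Ins1 (-0.22 ± 0.26, adjusted p = 0.692), Ins2 (-0.32 ± 0.27, adjusted p = 0.574), the glucagon gene Gcg (-0.13 ± 0.18, adjusted p = 0.749) and the somatostatin gene Sst (-0.68 ± 0.21, adjusted p = 0.0961) did not pass over all genes. The mean log2 CPM of the 8 hormone genes was 11.9 ± 0.195 in control and 11.2 ± 0.206 in miR-17-5p libraries, with every miR-17-5p library below every control (exact permutation p = 0.0179, adjusted p = 0.0774 over the lists). The hormone list gave a camera adjusted p of 3.3e-04, and an adjusted p of 0.294 with an estimated correlation.

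All 12 tested transcription factors of beta cell identity had fold changes below 0. By edgeR 0 of them passed over all genes, while 10 were lower adjusted over the list alone. Without miR-17-5p replicate 1, 4 were lower over all genes, and without replicate 2, 1 was. Pdx1, a master regulator of pancreas and beta cells, had a value of -0.60 ± 0.17 (adjusted p = 0.0600). Their camera adjusted p was 2.0e-05, and the adjusted p was 0.434 with an estimated correlation. Of 24 genes for glucose sensing and insulin secretion, Kcnj11, the pore of the ATP-sensitive potassium channel, fell by 0.52 ± 0.12 (adjusted p = 0.0337), and 9 were lower adjusted over the list alone. By edgeR 10 were lower without miR-17-5p replicate 1, and 0 without any control replicate or miR-17-5p replicate 4, 5 or 6. The camera adjusted p was 2.4e-05, and 0.434 was the adjusted p with an estimated correlation.

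Ribosomal protein genes had values above 0 in 41 of 41 tested members, of which 4 rose over all genes and 27 adjusted over the list alone. Rps20 was an example (0.75 ± 0.18, adjusted p = 0.0341). The 4 became 8 without miR-17-5p replicate 1, 2 without control replicate 1 or miR-17-5p replicate 2, and 0 by edgeR without control replicate 2 or 3 or miR-17-5p replicate 4 or 5. Their camera adjusted p was 2.5e-09, and the adjusted p was 0.451 with an estimated correlation. Genes that mature beta cells keep low rose in 2 of 15 members, 5 adjusted over the list alone, including the chemokine gene Cxcl12 (1.72 ± 0.37, adjusted p = 0.0227), with a camera adjusted p of 3.2e-04 and an adjusted p of 0.434 with an estimated correlation. The 2 became 5 without miR-17-5p replicate 1, 1 without miR-17-5p replicate 2, 5 or 6, and 0 by edgeR without control replicate 2 or 3 or miR-17-5p replicate 4. Cell cycle genes had values above 0 in 26 of 29 members. By edgeR 0 passed over all genes (1 without miR-17-5p replicate 1) and 2 adjusted over the list alone, with a camera adjusted p of 9.3e-05 and an adjusted p of 0.294 with an estimated correlation.

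Markers of other cell types were tested as well. Endothelial markers Cdh5, a junction cadherin (-1.88 ± 0.36), and Kdr, a receptor for vascular endothelial growth factor (-1.99 ± 0.44), fell, 2 of 13 members over all genes. Adjusted over the list alone 3 were lower and 1 was higher, Eng (0.68 ± 0.21), and 5 of the 13 had values above 0 (camera adjusted p = 0.0195, and adjusted p = 0.490 with an estimated correlation). The mean log2 CPM of the list was 3.03 ± 0.400 in control and 2.42 ± 0.713 in miR-17-5p libraries (SD, n = 3 and 5; exact permutation p = 0.232). The hemoglobin genes Hba2 (-2.34 ± 0.41) and Hbb (-2.92 ± 0.57) were among 3 of 4 red blood cell genes that fell, 3 adjusted over the list alone (camera adjusted p = 6.8e-04, and adjusted p = 0.294 with an estimated correlation). Duct markers fell in 1 of 10 members, 4 adjusted over the list alone. That member was Epcam, an epithelial adhesion molecule (-0.66 ± 0.13), and the list had a camera adjusted p of 0.00871 and an adjusted p of 0.294 with an estimated correlation. Markers of alpha, delta and PP cells fell in 1 of 9 members, Sstr3, a somatostatin receptor, with 3 adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.294 with an estimated correlation). All 16 macrophage and leukocyte markers had values above 0. By edgeR 0 passed over all genes and 0 over the list alone, with a camera adjusted p of 7.1e-04 and an adjusted p of 0.490 with an estimated correlation. Without control replicate 2, 2 were higher over all genes, and without miR-17-5p replicate 1, 1 was. The lower endothelial markers became 1 without control replicate 2 or 3 or miR-17-5p replicate 4 or 5, and the lower red blood cell genes 1 without control replicate 3 or miR-17-5p replicate 4. Both were 0 by edgeR without control replicate 1. For duct markers edgeR called 0 without control replicate 2 or 3 and 2 without miR-17-5p replicate 1 or 2, and for alpha, delta and PP markers 0 without control replicate 1 or 2 and 2 without miR-17-5p replicate 1.

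The other 13 lists did not pass the camera test. For acinar markers (0 of 10 called by edgeR, adjusted p = 0.134) and Schwann cell and neural markers (1 of 9, Cryab, adjusted p = 0.790) the test gave no difference from other genes. The same held for interferon-stimulated genes, which react to double-stranded RNA (1 of 30, Cxcl10, adjusted p = 0.291), and for inflammation genes (1 higher and 1 lower of 10, adjusted p = 0.790). Immediate early genes included 3 that fell, Egr1, Fos (-1.14 ± 0.27) and Btg2 (-0.75 ± 0.17), of 20 (adjusted p = 0.267). Signalling by insulin and mTOR had 1 higher member of 22, Eif4ebp1 (adjusted p = 0.904). Autophagy (22 tested, adjusted p = 0.476), the unfolded protein response (19, adjusted p = 0.664), glycolysis (18, adjusted p = 0.265), respiration (29, adjusted p = 0.790), microRNA machinery (17, adjusted p = 0.265) and replication-dependent histones (8, adjusted p = 0.0883) had 0 members called by edgeR over all genes. Adjusted over each list alone, 1 glycolysis gene was higher and 1 lower, 1 histone gene was lower, and 1 interferon gene and 1 immediate early gene were higher beside those that fell. These small counts also moved with single libraries. The Schwann cell and the insulin and mTOR lists had 0 called by edgeR without control replicate 2 or 3 or miR-17-5p replicate 4. Inflammation genes had 0 without control replicate 2 or 3 or miR-17-5p replicate 2, 4, 5 or 6, and 1 immediate early gene fell without any 1 control replicate or miR-17-5p replicate 4, 5 or 6. Without miR-17-5p replicate 1, 3 interferon genes and 2 immediate early genes were higher, 1 autophagy gene and 1 histone gene were lower, and the unfolded protein response and glycolysis lists each had 1 higher and 1 lower.

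The last list held known targets of the miR-17 seed family. Of 42 tested, 1 passed over all genes and it was higher, Lima1, an actin-binding protein (0.73 ± 0.18, adjusted p = 0.0406), while 2 were higher adjusted over the list alone. By edgeR 0 passed without any 1 control replicate or miR-17-5p replicate 4, 5 or 6, and 2 were higher and 1 lower without miR-17-5p replicate 1. The list's median log2 fold change was -0.14, with a camera adjusted p of 0.247. Among its best known members Cdkn1a (0.20 ± 0.29, adjusted p = 0.770), E2f1 (0.45 ± 0.48, adjusted p = 0.668), Bcl2l11 (0.12 ± 0.61, adjusted p = 0.939) and Tgfbr2 (0.63 ± 0.51, adjusted p = 0.558) did not pass. Across the 26 lists 13 passed camera, 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) and 6 passed fry.

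The number of genes called in mRNA depended on single libraries. It was 85 without control replicate 3 and 107 without control replicate 2, 189, 237 and 249 without miR-17-5p replicates 4, 5 and 6, and 816 without replicate 1. DESeq2 called 887 genes and limma-voom 1001.

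The second comparison asked which transcripts changed in the Ago2-bound RNA. Several matrix genes had small p values. Bgn, the matrix proteoglycan biglycan, rose from 213 ± 26.6 CPM in control to 883 ± 130 CPM in miR-17-5p RISC libraries (SD, n = 3 and 4), and Serpinh1, a collagen chaperone, from 207 ± 42.0 to 986 ± 160 CPM. Col1a1, a collagen chain, rose from 1534 ± 401 to 7794 ± 2218 CPM. Lgals3, galectin 3, fell from 653 ± 188 to 171 ± 34.5 CPM. Insulin transcripts did not pass the test.

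In edgeR's quasi-likelihood test 35 of 9443 genes passed, 32 higher and 3 lower. Bgn (2.06 ± 0.21) and Serpinh1 (2.26 ± 0.23) had the smallest p (edgeR adjusted p = 0.0115). They were followed by Tnc, the matrix protein tenascin C (2.03 ± 0.22, adjusted p = 0.0135), Fstl1, a follistatin-like secreted protein (2.37 ± 0.29, adjusted p = 0.0191), and Lrp1, an endocytic receptor (1.56 ± 0.20). Col1a1 (2.35 ± 0.29), Vcl, the adhesion protein vinculin (1.40 ± 0.18), and Itga8, an integrin (2.46 ± 0.31), also rose. The 3 lower genes were Lgals3 (-1.93 ± 0.27, adjusted p = 0.0257), Gyltl1b, a glycosyltransferase (-1.82 ± 0.27, adjusted p = 0.0257), and Crispld1 (-1.20 ± 0.19, adjusted p = 0.0355).

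**Figure D3:**
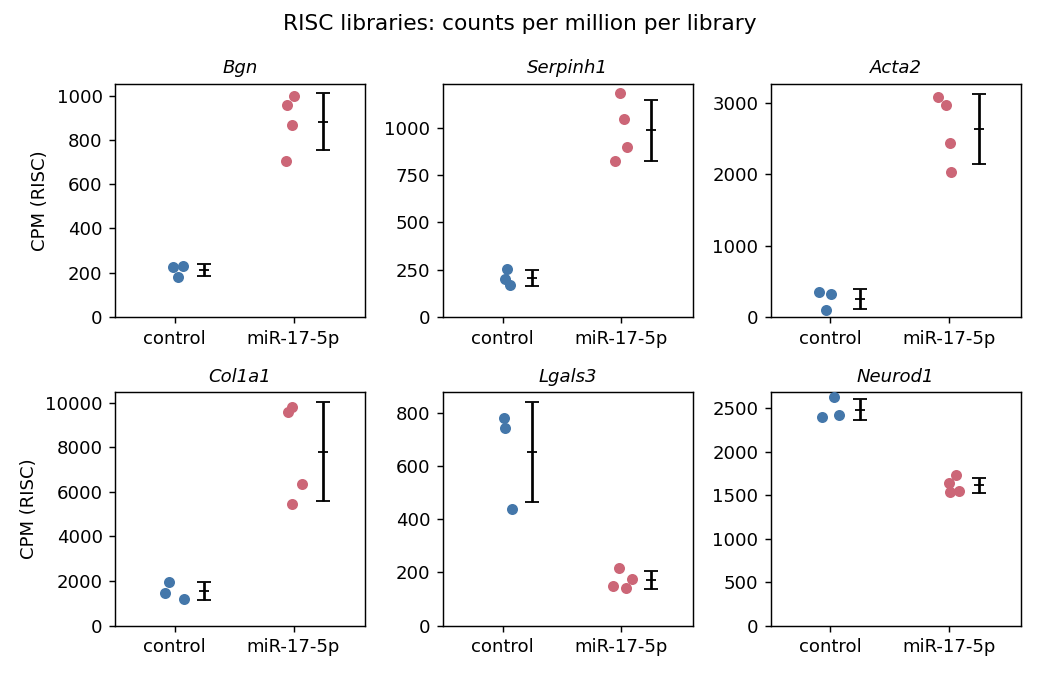
CPM (vertical axes, from 0) of 6 genes in the RISC libraries, control (n = 3) and miR-17-5p (n = 4); points are libraries, and bars show the mean and SD. Bgn, Serpinh1, Acta2 and Col1a1 lie higher with miR-17-5p and Lgals3 lies lower; Neurod1 lies lower with an edgeR adjusted p of 0.0725.

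In the RISC libraries 6 of 17 stellate and fibroblast genes rose, 9 adjusted over the list alone. Examples were Acta2 (3.38 ± 0.45), Col5a1, a collagen chain (1.86 ± 0.25), and Sparc (1.85 ± 0.26), each with an adjusted p of 0.0257. The list's camera adjusted p was 0.0233, and the adjusted p was 0.549 with an estimated correlation. The number of stellate members called was 0 without control replicate 1 or miR-17-5p replicate 2, 5 or 6, and 10 without control replicate 2. Macrophage and leukocyte markers rose in 1 of 12 members, 5 adjusted over the list alone. That member was Lcp1, a leukocyte actin-bundling protein, at 0.0214 CPM in control and 58.5 CPM in miR-17-5p libraries. The 1 marker called became 6 without control replicate 2, 2 without miR-17-5p replicate 4, and 0 by edgeR without control replicate 1 or miR-17-5p replicate 2, 5 or 6. The camera adjusted p was 3.5e-04, and the adjusted p was 0.332 with an estimated correlation. Atp5a1, a subunit of ATP synthase, was the only one of 25 respiration genes called (3.11 ± 0.45, adjusted p = 0.0257), with 4 adjusted over the list alone. It became 4 genes without miR-17-5p replicate 4, 2 without control replicate 2, and 0 by edgeR without control replicate 1 or miR-17-5p replicate 2, 5 or 6.

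By camera 3 islet cell lists lay lower than other genes in RISC, while their scores per library overlapped between the groups. The mean log2 CPM was 9.28 ± 0.764 in control and 8.87 ± 0.215 in miR-17-5p libraries for hormones, 6.58 ± 1.21 and 6.83 ± 0.200 for beta cell transcription factors, and 7.86 ± 0.407 and 7.84 ± 0.222 for glucose sensing and secretion (SD, n = 3 and 4; exact permutation p = 0.4, 0.886 and 0.943). Of 7 hormone genes 0 passed in edgeR over all genes and 1 was lower adjusted over the list alone. Iapp, the amyloid peptide gene of beta cells, had a value of -1.61 ± 0.40 (adjusted p = 0.0725), Ins1 -0.38 ± 0.21 (adjusted p = 0.441) and Ins2 -0.39 ± 0.25 (adjusted p = 0.544). Gcg (-0.15 ± 0.37, adjusted p = 0.978) and Sst (-0.55 ± 1.48, adjusted p = 0.981) did not pass either. Beta cell transcription factors had 0 of 12 members called by edgeR and 4 lower adjusted over the list alone, with Neurod1, a factor of beta cell differentiation, at -0.62 ± 0.15 (adjusted p = 0.0725). Camera gave both lists an adjusted p of 0.00695, and the adjusted p was 0.332 with an estimated correlation. Genes for glucose sensing and secretion had 0 of 24 called by edgeR and 1 lower adjusted over the list alone (camera adjusted p = 3.5e-04, and adjusted p = 0.332 with an estimated correlation). Without control replicate 2, 2 of these were higher and 1 was lower over all genes, and 2 beta cell transcription factors were lower.

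For known targets of the miR-17 seed family edgeR called 0 of 43 over all genes and 1 higher adjusted over the list alone, with a camera adjusted p of 0.707. The list's mean log2 CPM was 4.38 ± 0.624 in control and 5.85 ± 0.184 in miR-17-5p libraries (SD, n = 3 and 4; exact permutation p = 0.0286, adjusted p = 0.0527 over the lists). The same p was found for 13 of 24 lists, all with higher scores in miR-17-5p libraries, among them cell cycle, autophagy, respiration, ribosomal protein, stellate and macrophage genes. Without control replicate 2, 5 were higher and 1 was lower, and without miR-17-5p replicate 4, 1 was higher. Lima1 had a value of 1.07 ± 0.21 (adjusted p = 0.0725) and Cdkn1a 1.13 ± 0.36 (adjusted p = 0.107). Bcl2l11 (2.05 ± 2.48, adjusted p = 0.898) and Tgfbr2 (1.35 ± 1.29, adjusted p = 0.824) had wide errors, and E2f1 had 0 counts in control RISC libraries (adjusted p = 0.137). Across the lists 5 passed camera, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 13 passed fry.

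The count of 35 genes fell to 0 without miR-17-5p replicate 2, 5 or 6 (1139, 1153 and 1268 at an unadjusted p under 0.05), and was 26, 1225 and 122 without control replicates 1, 2 and 3 and 548 without miR-17-5p replicate 4. DESeq2 called 1305 genes and limma-voom 20; on simulated RISC counts 58.4% of DESeq2's calls were false.

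The third comparison asked which genes fell in mRNA while rising in Ago2-bound RNA. Of 9337 genes tested in both fits, edgeR called 0 that way, against 0.260 if the lists were independent, and 57 at an unadjusted p under 0.05 in both. DESeq2 called 6. In contrast, 26 genes rose in both, against 1.14 for independent lists (Fisher's exact p across genes = 7.0e-33). Among them, picked as examples after their values were seen, were the cytoskeletal genes Acta2, Actb, Flna, Tln1, Vcl and Vim, the collagens Col1a1, Col4a1, Col5a1, Col5a2 and Col11a1, and Fn1, Sparc, Bgn and Serpinh1. Lgals3 was the only gene lower in both. Fisher's p treats genes as independent and measures no spread between libraries. If mRNA and RISC libraries came from shared cultures, a difference between cultures would enter both lists.

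Across the 9337 genes the log2 fold changes in mRNA and RISC had a Pearson r of 0.19 and a Spearman rho of 0.22; genes are not independent replicates. Of the 76 genes lower in mRNA 32.9% had a RISC fold change above 0, against 59.0% of all genes and 90.1% of the 334 higher in mRNA. The genes nearest to falling in mRNA and rising in RISC included Ckmt1b, mitochondrial creatine kinase, and Cxcr4, a chemokine receptor, both with wide errors in RISC. Ckmt1b had values of -0.81 ± 0.21 in mRNA (adjusted p = 0.0477) and 8.18 ± 2.46 in RISC (adjusted p = 0.0915). Cxcr4 had values of -1.31 ± 0.32 in mRNA (adjusted p = 0.0376) and 8.48 ± 2.81 in RISC (adjusted p = 0.129). Sorcs2 had values of -0.67 ± 0.14 in mRNA and 1.04 ± 0.43 in RISC (adjusted p = 0.206 in RISC), and Ezr, the membrane linker ezrin, -0.60 ± 0.12 and 0.95 ± 0.52 (adjusted p = 0.412 in RISC). The 26 shared higher genes became 14 without control replicate 1 or 3, 48 without control replicate 2, and 0 without miR-17-5p replicate 2, 5 or 6. They numbered 184 with DESeq2 and 132 by edgeR at an adjusted p under 0.1 in both.

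The fourth comparison asked which genes changed more in RISC than in mRNA, as the difference of both log2 fold changes in one model of all 15 libraries. Stat3, a transcription factor and known target of the miR-17 family, lay at 283 ± 69.3 CPM in control and 418 ± 23.6 CPM in miR-17-5p RISC libraries, while its mRNA was 411 ± 16.9 CPM in control and 345 ± 29.8 CPM with miR-17-5p (SD; n = 3, 4, 3 and 5). Vim, the intermediate filament vimentin, rose from 56.4 ± 37.6 to 556 ± 144 CPM in RISC and lay at 877 ± 250 and 1763 ± 413 CPM in mRNA. Atf4, a transcription factor of the stress response, went the other way, with 152 ± 5.97 and 74.5 ± 11.7 CPM in RISC and 171 ± 7.83 and 176 ± 19.4 CPM in mRNA. Many of the leading genes had almost no counts in control RISC libraries.

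EdgeR called 1533 of 11418 genes, 1488 higher and 45 lower in RISC relative to mRNA, and 1023 of the higher genes had 0 counts in all 3 control RISC libraries. In those libraries 3 counts correspond to 0.224, 0.346 and 0.717 CPM. The model gave each gene the same spread in both library types. Fitted alone, the common coefficient of variation was 0.305 in mRNA and 1.23 in RISC, so p-values of this comparison may be too small. The 8 higher genes with the smallest p included the ribosomal protein genes Rpl22, at 0.0360 CPM in control and 41.9 ± 12.6 CPM in miR-17-5p RISC (adjusted p = 2.6e-06), Rpl37 (0.0185 and 7.73 CPM) and Rps29 (0.0371 and 13.8 CPM). Mif, a cytokine, had 0 and 26.1 ± 10.5 CPM and Fkbp9, a peptidyl-prolyl isomerase, 0 and 68.0 ± 16.6 CPM, while Hint1 (0.0185 and 10.3 CPM), Nudc (0.0731 and 22.6 CPM) and Rbm42 (0.0360 and 23.9 CPM) had a few control counts. Only genes with a mean of at least 500 counts per library, a filter added after seeing the data, left 29 of 2763 called, 20 higher and 9 lower. Of those 29 genes 15 still had a control RISC library at 0.

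Genes with counts in both kinds of RISC library gave smaller folds. Stat3 had a value of 0.82 ± 0.21 (adjusted p = 0.0184), Fyco1, an autophagosome transport protein and known family target, 1.56 ± 0.46 (adjusted p = 0.0342), and Vim 2.29 ± 0.49 (adjusted p = 0.0058). The glycolytic genes Pkm (1.20 ± 0.33, adjusted p = 0.0254) and Aldoa (1.13 ± 0.32, adjusted p = 0.0298) and Atp5a1 (3.21 ± 0.37, adjusted p = 9.1e-05) were also higher in RISC relative to mRNA. The lower genes were led by LOC100188932 (-2.02 ± 0.34, adjusted p = 9.6e-04), Rpl27 (-1.80 ± 0.38, adjusted p = 0.0049) and Rpl28 (-1.66 ± 0.35, adjusted p = 0.0050). After Atf4 (-1.07 ± 0.23, adjusted p = 0.0053) came Atp5g1, an ATP synthase subunit (-2.37 ± 0.50), Otub1, a deubiquitinase (-1.38 ± 0.33), Strn3, a striatin (-1.51 ± 0.38), and Slmap (-1.24 ± 0.32).

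Of 43 known family targets 6 were higher relative to mRNA, 8 adjusted over the list alone, with a camera adjusted p of 0.473. The 6 included Stat3, Fyco1, E2f1 (adjusted p = 0.0488, with 0 counts in control RISC) and Gpr137b (0 CPM in control and 14.3 ± 1.90 CPM in miR-17-5p RISC, adjusted p = 1.4e-04). The 6 became 10 without control replicate 1 and 3 without miR-17-5p replicate 5. With the replicate number as a block edgeR called 0 of the 43, and 0 adjusted over the list alone. Among genes with a mean of at least 500 counts, edgeR called 0 of 23 family targets (3 at an unadjusted p under 0.05), and Stat3 had a value of 0.63 ± 0.22 (adjusted p = 0.219). Cdkn1a (0.90 ± 0.49, adjusted p = 0.296), Bcl2l11 (1.88 ± 2.27, adjusted p = 0.789) and Tgfbr2 (0.66 ± 1.46, adjusted p = 0.925) did not pass. Neither did Ins1 (-0.17 ± 0.30, adjusted p = 0.888), Ins2 (-0.09 ± 0.36, adjusted p = 0.980), Gcg (-0.02 ± 0.42) or Sst (0.10 ± 1.25). Of 26 lists 1 passed camera, acinar markers, lower in direction with 0 of 11 members called by edgeR over all genes and 0 over the list alone (adjusted p = 0.00846, and adjusted p = 0.800 with an estimated correlation). With an estimated correlation 0 lists passed (0 at an unadjusted p under 0.05), and 14 passed fry.

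The number of genes called in RISC relative to mRNA was 2452 without control replicate 2, and limma-voom called 0 (1334 at an unadjusted p under 0.05) and DESeq2 2217. The median fitted fold change of all genes was 0.40, 0.27 with DESeq2 size factors, 1.53 with limma-voom and -0.06 with a minimum of 500 counts. It was 0.87 without control replicate 1 and 0.95 without control replicate 2.

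The fifth comparison asked which transcripts the Ago2 pulldown held relative to poly(A) RNA in control cells. The labels state poly(A) selection for the mRNA libraries and none for the RISC libraries. Neurod1 lay higher in RISC, at 2229 ± 143 CPM against 387 ± 36.0 CPM in mRNA (SD, n = 3 and 3). Tnrc6b, a partner of Argonaute in silencing, lay at 837 ± 88.2 against 124 ± 37.1 CPM. Insulin and ribosomal protein transcripts lay lower, with Ins1 at 7842 ± 2221 against 271870 ± 27771 CPM and Rpl32 at 27.9 ± 1.43 against 603 ± 45.2 CPM.

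EdgeR called 2870 of 10170 genes, 606 higher and 2264 lower in RISC, and 1562 of the lower genes had 0 counts in all control RISC libraries. Neurod1 had a log2 fold change of 2.52 ± 0.14 (edgeR adjusted p = 0.0037). Zfp652, a zinc finger protein (2.88 ± 0.19), Tnpo1, a nuclear import receptor (2.37 ± 0.16), and Nfat5, an osmotic stress factor (2.40 ± 0.17), had adjusted p values of 0.0043. Secisbp2l (2.44 ± 0.18), Slmap (2.77 ± 0.21), Hipk3, a kinase (2.58 ± 0.20), and Tjp1, the tight junction protein ZO-1 (2.51 ± 0.20), were also higher. The lower genes were led by Rpl32 (-4.43 ± 0.17, adjusted p = 0.0034), Ins1 (-5.12 ± 0.26, adjusted p = 0.0037) and Ins2 (-4.87 ± 0.26, adjusted p = 0.0037). Atp5a1 (-4.31 ± 0.22), Rpl41 (-3.56 ± 0.19), Snhg11, a small nucleolar RNA host gene (-3.68 ± 0.21), and the granule protein genes Chga (-2.15 ± 0.13) and Resp18 (-1.90 ± 0.12) were lower as well.

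Ribosomal protein genes were lower in RISC in 18 of 41 members, 31 adjusted over the list alone, and 0 were higher by edgeR. Rps23, with 0 counts in control RISC, was at least 1157-fold lower against a floor of 3 counts per library. Among genes with a mean of at least 500 counts, Rps23 was higher with miR-17-5p in RISC relative to mRNA (9.04 ± 0.90, edgeR adjusted p = 1.1e-04). For the ribosomal protein list the camera adjusted p was 2.1e-04, and the adjusted p was 0.272 with an estimated correlation. Respiration genes were lower in 10 of 29 members, 10 adjusted over the list alone, with Ndufb8, a complex I subunit, at least 452-fold lower (camera adjusted p = 0.0205, and adjusted p = 0.272 with an estimated correlation). Hormone genes were lower in 6 of 8 members, 7 adjusted over the list alone, including Iapp (1881 ± 145 CPM in mRNA and 470 ± 64.6 CPM in RISC) and Gcg (-1.58 ± 0.33), while Sst did not pass (-4.88 ± 1.75, adjusted p = 0.105). Their camera adjusted p was 0.0359, and the adjusted p was 0.539 with an estimated correlation. Glycolysis genes were lower in 6 of 18 members, 6 adjusted over the list alone, with a camera adjusted p of 0.262.

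In the insulin, PI3K and mTOR list 5 members were higher and 1 was lower of 22, with 7 and 2 adjusted over the list alone. Irs1, an insulin receptor substrate (2.97 ± 0.45), Igf1r (2.27 ± 0.36) and Foxo1 (2.53 ± 0.32) were higher (camera adjusted p = 2.9e-04, and adjusted p = 0.248 with an estimated correlation). In the microRNA machinery list 5 were higher and 1 was lower of 17, and the same numbers held adjusted over the list alone. Tnrc6a (1.97 ± 0.23), Tnrc6b (2.75 ± 0.27), Dcp1a, a decapping factor (3.26 ± 0.32), and Ddx6, an RNA helicase of silencing (1.64 ± 0.27), were higher (camera adjusted p = 7.4e-04, and adjusted p = 0.272 with an estimated correlation). Beta cell transcription factors were higher in 2 of 12 members, 2 adjusted over the list alone, Neurod1 and Rfx6 (2.06 ± 0.39), with a camera adjusted p of 0.0315 and an adjusted p of 0.579 with an estimated correlation. Transforming growth factor beta and bone morphogenetic protein signalling had 3 higher and 1 lower member of 24, with 1 and 1 adjusted over the list alone, among them the receptor gene Bmpr2 (2.19 ± 0.45). The camera adjusted p was 0.0193, and the adjusted p was 0.272 with an estimated correlation.

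Of the known family targets 3 were higher and 5 lower of 42, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.101). E2f1, with 0 counts in control RISC, was at least 25.6-fold lower (adjusted p = 0.0191). Cdkn1a (0.22 ± 0.54, adjusted p = 0.869), Bcl2l11 (0.63 ± 2.02, adjusted p = 0.900) and Tgfbr2 (0.60 ± 1.87, adjusted p = 0.898) did not pass. Across the lists 7 passed camera, 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) and 19 passed fry.

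Without control replicate 1 edgeR called 0 genes between library types (3565 at an unadjusted p under 0.05), DESeq2 called 3742 with all libraries and limma-voom 3871, and a mean of at least 50 counts per library left 1254. So the members of each list were also 0 by edgeR without that replicate. Without control replicate 2, the insulin, PI3K and mTOR list and the microRNA machinery list each had 3 higher, and 0 were higher by edgeR among transforming growth factor beta genes and family targets. Without control replicate 3, 10 glycolysis genes were lower and 1 transforming growth factor beta gene was higher. With a mean of at least 500 counts 466 genes were higher and 327 lower. The median fitted fold change of all genes was -0.69, and it was -0.87 with DESeq2 size factors, -0.58 with upper quartile factors, -2.89 with limma-voom, -1.41 with no filter and 0.08 with the minimum of 500.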

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

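Of the tests below, the counts of other splits were planned, and the 7 other tests were chosen after the result was seen. Among 179 values tested within groups of 4 or 5 libraries, 13 had a library far from the others of its group (7.26%, where chance gives about 1 in 20).

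In mRNA, miR-17-5p replicate 1 had 21.1 M counts (others 5.87 M to 9.54 M) and Ins1 at 277026 CPM (others 157177 to 182139), and replicate 2 had a cell cycle score of 4.36 (others 3.94 to 4.04). In RISC, miR-17-5p replicate 6 stood apart most often. Its 10 most abundant genes took 47.2% of counts (others 32.9% to 34.4%), Rn45s 42.6% (26.6% to 28.2%), its stellate score was 8.73 (8.36 to 8.37), and Rpl37 lay at 6.00 CPM (9.93 to 10.5), Tnrc6a at 439 CPM (655 to 669) and Ddx6 at 199 CPM (284 to 301). Replicate 2 had 0.308% ambiguous alignments (0.162% to 0.167%), replicate 4 a beta cell transcription factor score of 6.53 (6.89 to 6.95) and a histone score of 1.04 (2.55 to 2.79), and replicate 5 had Aldoa at 552 CPM (646 to 662).

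The first pattern weighed was the rise of stellate and contractile genes in mRNA. Of 56 splits of the 8 libraries 1, the real one, gave as many called genes (429, highest other 3). The share of 1 in 56 is the smallest these splits allow and argues against chance for that count. Splits cannot part the transfection from other differences between the groups. For the stellate score itself chance was not excluded (exact permutation p = 0.0536, adjusted p = 0.169 over the lists). A lower share of endocrine cells alone would raise endothelial and stellate markers alike. The stellate minus endothelial score went from 4.83 ± 0.22 to 6.26 ± 0.39 (SD, n = 3 and 5; exact permutation p = 0.0179, all miR-17-5p libraries above all controls). The endothelial list was chosen as reference after the data were seen, and scores of other cell types went both ways. Macrophage (1.15), acinar (0.912) and Schwann cell (0.258) scores were higher with miR-17-5p, and duct (-0.502) and red blood cell (-2.10) scores were lower. This test alone therefore cannot decide, and a lower endocrine share stays open. More stellate cells may explain the rise and stay open. They would lower no member, and Mgp (-0.62 ± 0.45) and Postn (-0.50 ± 0.27) lay below 0 without passing (smallest edgeR adjusted p over the list 0.125). Under 2 alternatives 1 member was called lower beside 11 higher: limma-voom, and edgeR without miR-17-5p replicates 1 and 2 together. Scaling by a few abundant genes is argued against by the alternative fits. With DESeq2 size factors, upper quartile factors, and library sizes without Ins1, Ins2, Rn45s and Rn28s, 10 of 17 stellate genes stayed higher each time. Their median log2 fold changes were 0.920, 0.946 and 0.916, against 0.928 with the first settings. A factor per library cancels in the stellate score relative to all genes, which lay at 3.81 ± 0.261 and 4.55 ± 0.429 (SD, n = 3 and 5; exact permutation p = 0.0714). That difference was 0.742, against 0.818 for the score itself, and its p alone did not decide. A changed state of stellate cells was not tested.

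The second pattern was the 1488 genes higher in RISC relative to mRNA. Of 56 splits 2 gave as many called genes as the real 1533. The highest other called 1819, with treated replicate 1, which has no RISC library, in place of control replicate 2. This points to a structure of the samples. The share of 2 in 56 is under 0.05, but another split called more genes than the real one, so chance is not excluded. The other 2 splits that put treated replicate 1 with 2 controls called 816 and 1065, and the highest with 3 RISC libraries on the control side called 425. Fewer distinct molecules in control RISC libraries stay open. At one depth, of the genes with at least 20 counts in 1 library, on average 20.3% were absent from another library of the same group in controls and 4.26% with miR-17-5p (exact permutation p = 0.0571). Sequencing depth alone is argued against by the genes detected at one depth (exact permutation p = 0.0286). Recruitment of miR-17 family targets stays open: 6 of 43 targets (14.0%) were higher against 13.0% of other genes (Fisher's exact p across genes = 0.820, odds ratio 1.08, interval 0.373 to 2.59).

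The third pattern concerned family targets in RISC among genes with a mean of at least 500 counts. The 28 targets had a median log2 fold change of 0.34 against -0.04 for all such genes (camera p = 0.0295, p = 0.0579 with an estimated correlation). Per library, targets relative to all such genes lay at 0.203 ± 0.195 in control and 0.273 ± 0.0904 in miR-17-5p libraries (SD, n = 3 and 4; exact permutation p = 0.6), so recruitment stays open.

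Of the other counts, 1 of 35 splits in RISC gave 35 genes (highest other 0). With treated replicate 1 on the control side, 2 RISC libraries against 5 gave up to 96. For genes higher in both mRNA and RISC 1 of 56 gave 26 (highest other 0). The other splits called at most 3 genes in mRNA, so they could hardly share any, and this count is no separate test. The share of 1 in 35 is under 0.05, the smallest these splits allow, and argues against chance for the RISC count. That count still fell to 0 without miR-17-5p replicate 2, 5 or 6. Between library types 1 of 10 splits gave 2870 (highest other 0), and 10 splits are too few for a share under 0.05.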

How the results depend on the processing

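Tests chosen after the result was seen were the minimum of 500 counts, library sizes without insulin and ribosomal genes, the covariate, and leaving out 2 replicates together. In simulated RISC counts edgeR recovered 32.6% of 64-fold changes (8800 genes), against 100% in mRNA (10886 genes). DESeq2 size factors, upper quartile factors, no filter, minimums of 50 and 500 counts and library sizes without insulin and ribosomal genes kept the mRNA count at 336 to 512. Seed site tests were not run. Of 816 single gene values in mRNA under the alternatives 669 kept direction and side of the threshold, 125 lost and 10 gained the call and 12 reversed; in RISC it was 320, 65, 7 and 3 of 395, relative to mRNA 441, 81, 1 and 26 of 549, and between library types 362, 41, 2 and 6 of 411. All reversed genes were uncalled with the first settings. The cause was not tested for any change below, except that fewer genes were tested under a minimum count.

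The mRNA count of 429 was 887 with DESeq2, 1001 with limma-voom, 33 with the covariate (25 shared; the median of higher genes went from 1.20 to 0.66 and of lower genes from -0.73 to -0.53), 879 without miR-17-5p replicates 1 and 2 together, and 85 to 816 leaving out single libraries (85 without control replicate 3, 816 without miR-17-5p replicate 1). The RISC count of 35 was 1305 with DESeq2, 20 with limma-voom and 0 to 1225 leaving out libraries (0 by edgeR without miR-17-5p replicate 2, 5 or 6, with 1139, 1153 and 1268 at an unadjusted p under 0.05; 1225 without control replicate 2). Relative to mRNA 1533 became 0 with limma-voom (1334 at an unadjusted p under 0.05; DESeq2 2217), 29 with a minimum of 500, and 1155 to 2452 leaving out libraries (2452 without control replicate 2). Between library types 2870 became 1254 and 793 with minimums of 50 and 500, and 0 to 3114 leaving out libraries (0 by edgeR without control replicate 1, 3565 at an unadjusted p under 0.05; DESeq2 3742 with all libraries). Genes lower in mRNA and higher in RISC numbered 0 by edgeR (57 at an unadjusted p under 0.05), 5 at an adjusted p under 0.1, 6 with DESeq2, and 0 to 2 leaving out libraries (1 without control replicate 2, 2 without miR-17-5p replicate 4). Leaving out libraries gave medians of all genes of 0.35 to 0.95 relative to mRNA and -1.04 to -0.77 between library types.

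Gene lists called by camera were 13 in mRNA, 0 with an estimated correlation and 6 by fry; 5, 0 and 13 in RISC; 1, 0 and 14 relative to mRNA; and 7, 0 and 19 between library types. At an unadjusted p under 0.05 the estimated correlation gave 4, 2, 0 and 4.

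With the replicate number as a block, the mRNA count was 0 by edgeR (461 at an unadjusted p under 0.05), the count relative to mRNA 30 (median of all genes 1.47), between library types 338 (171 higher and 167 lower, median -2.38), and lists relative to mRNA 2. Macrophage markers in mRNA had 7 of 16 values above 0 (median -0.07). Only numbers 1 and 2 occur in both mRNA groups, so under the block the mRNA fold changes rest on those libraries alone. These blocked mRNA values therefore cannot decide whether the mRNA calls hold. Libraries with the same number had correlations of -0.34 and -0.10 between transfections in mRNA, -0.01 to 0.04 between library types in control cells and -0.06 to 0.11 in miR-17-5p cells, so the counts give no sign of pairs, and whether the numbers mark shared cultures stays open. In RISC alone, no paired analysis was possible because the groups share only number 2. Under the block Tgfbr2 in mRNA was -0.61, relative to mRNA Ins1 was 0.033 and Ins2 0.12, and between library types Bcl2l11 was -3.90 and Tgfbr2 -0.58.

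In mRNA, limma-voom gave E2f1 -0.11 and Bcl2l11 -0.0065, the covariate Ins1 0.27, Ins2 0.32, Cdkn1a -0.57, E2f1 -0.024 and Tgfbr2 -1.13, and without replicates 1 and 2 Bcl2l11 was -0.18; leaving out libraries gave Bcl2l11 -0.18 to 0.32 and Gcg -0.25 to 0.059. In RISC, limma-voom gave Sst 1.40, and leaving out libraries gave Gcg -0.51 to 0.25. Relative to mRNA, Sst was -0.011 with DESeq2 size factors, -0.0074 with DESeq2 and -0.052 with a minimum of 500. A minimum of 50 gave Ins1 0.014, Gcg 0.14 and Ins2 0.091, limma-voom Gcg 0.0085, and numbers with both types Ins1 0.0041, Gcg 0.044 and Ins2 0.089. Leaving out libraries gave Sst -0.31 to 0.65, Ins1 -0.26 to 0.32, Gcg -0.42 to 0.62 and Ins2 -0.19 to 0.36. Between library types, limma-voom gave Bcl2l11 -2.99 and Tgfbr2 -1.47; leaving out libraries gave Bcl2l11 -5.48 to 1.38 and Cdkn1a -0.034 to 0.61.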

Other observations

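The test in this part was chosen after the result was seen. The genes that led the difference between library types in control cells were looked up in the miR-17-5p libraries, which that comparison did not use. All 16 lay on the same side there, with all 4 RISC libraries apart from all 5 mRNA libraries. The look-up covers these 16 genes only, each with a mean log2 CPM of at least 4. Sizes moved both ways: Atp5a1 differed less than in control cells (mean log2 difference -1.20) and Snhg11 more (-5.34). Neurod1 lay at 244 ± 78.3 CPM in mRNA and 1355 ± 78.2 CPM in RISC libraries, and Hipk3 at 63.5 ± 7.66 and 395 ± 74.6 CPM (SD, n = 5 and 4). Ins1 lay at 221702 ± 58240 and 5663 ± 594 CPM, Rpl32 at 759 ± 82.5 and 30.3 ± 24.2 CPM and Snhg11 at 259 ± 61.4 and 9.26 ± 10.3 CPM. Each of the 16 genes had an exact permutation p of 0.00794 (adjusted p = 0.00794), the smallest that 126 splits can give.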
